A study of Mus musculus with 42 samples.

How the data were processed

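The series measured RNA by sequencing in 42 libraries from the renal cortex of 12-week-old mice with an obstructed ureter. The proximal tubule fraction (PT) was RNA bound to anti-GFP beads, the method known as translating ribosome affinity purification. The other fraction is labelled total kidney (Total), and the labels do not say whether it is the unbound part. Kidneys were taken at day 5 and day 10 of obstruction, and contralateral kidneys served as controls, their day not given. The 12 groups of sex, state and fraction held 4 male or 3 female libraries, grouped by the labels, and every column was mapped to its sample.

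The authors named STAR 2.0.4b, Subread and featureCounts 1.4.5, and gave no genome build, annotation or strand setting. The deposited tables hold raw counts and RPKM for 40701 gene symbols, of which 12632 were 0 in every library. The values were checked: counts per M counts (CPM) divided by RPKM gave 1 length per gene in all libraries, within a relative deviation of 0.00043, for 28069 genes. GENCODE M21 was used for gene types and overlaps by symbol alone (39727 symbols matched, 5272 of them long noncoding).

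Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low genes were removed with filterByExpr by group, TMM factors were computed and a robust quasi-likelihood model with 1 mean per group was fitted to the PT libraries, to the Total libraries and, for comparisons across fractions, to all libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold. The 20 comparisons were day 5 and day 10 against contralateral and day 10 against day 5 in PT and in Total, with the sexes averaged at equal weight; days 5 and 10 in PT of each sex; PT against Total in each state; females against males in PT in each state; and the interactions of fraction and of sex with day 5 and day 10. Printed CPM use the TMM-scaled library size. For a gene with 0 counts on 1 side a lower bound of the fold is given. Its floor is 3 counts in a library of that side's mean size. For 1 to 3 counts summed over a side the ratio is given with a counting interval. Bounds and ratios are therefore not comparable.

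The 27 gene lists were written down before the data were examined, as were the comparisons, thresholds and the alternatives other than those named below. They covered PT solute carriers, gluconeogenesis and PT metabolism, fatty acid oxidation, the respiratory chain, tubule injury and repair, chemokines, the NF-kB pathway, interferon response, complement and acute phase, class II antigen presentation, profibrotic factors, p53 targets, cell cycle, ATF4 and unfolded protein response, immediate early genes, named long noncoding RNAs, sex-biased and sex chromosome genes, and markers of fibroblasts, macrophages, lymphocytes, endothelium, podocytes, loop of Henle and distal tubule, collecting duct and erythrocytes. Vcam1, Atf3, Btg2 and Egf each stand on 2 lists. Lists with at least 3 tested members were tested by camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry.

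The genes named are 16 marker genes of obstruction, 11 of the fractions (1 of them not described) and 10 of sex fixed beforehand; in each comparison the 6 largest rises and falls with at least 5 CPM as the mean of 1 sex on 1 side and no overlap between the libraries of the sides within a sex; per list described, the largest called members each way; and the 3 long noncoding RNAs with the largest rise and fall at 1 CPM or more. The rule on overlap was not applied to the interactions, and between the sexes it was taken over all libraries of the sides. Il34 and Spp1 between the sexes, Malat1, Cyp4a12a per sex and the clock genes were chosen after their values were seen.

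Alternatives were RLE and upper-quartile factors or library size only; no filter or a filter of 5 CPM in 3 libraries; DESeq2 1.42.0; limma-voom; limma with a trend on log2(RPKM + 1) of genes with a mean RPKM of 0.5 or more in a group; only the compared groups; the replicate number as a block; other thresholds; and each library left out in turn. Chosen after the data were seen were the Lars2 level and a clock score (mean log2 CPM of an Arntl arm of clock genes minus that of a Per arm) as covariates, a term for a split of the PT libraries that follows Lars2, fits within each side of it, and Total without its libraries of lowest Lars2. The Arntl arm held Arntl, Npas2, Clock, Nfil3 and Cry1, and the Per arm the other clock genes. Replicate numbers were taken as pairs where all 7 numbers correlated above 0.1 with their own number and best with it: contralateral with day 10 in Total, and PT with Total in contralateral and day 10 kidneys.

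Total counts ran from 9.31 to 43.6 M per library. On counts simulated from these libraries, the test recovered 66% of planted 2-fold and 97% of 4-fold changes for PT day 5 against contralateral, 35% and 91% for the sexes in contralateral PT, and 6% and 66% for the interaction of sex with day 10. A gene counted as recovered at an adjusted p under 0.05 in the planted direction, without the 2-fold minimum. These shares are therefore upper limits for calls. Replicates varied beyond counting noise, with chi-square over degrees of freedom from 16.3 to 327. Left out were splicing and isoforms, which gene counts do not hold, and sex comparisons in Total, which were not planned. Figures were drawn with matplotlib 3.10.9.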

Results

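The libraries set ribosome-bound RNA of the proximal tubule (PT) and total kidney RNA (Total) of obstructed mouse kidneys against those of contralateral kidneys, with 4 male and 3 female libraries in each state. Total counts per library ran from 9.31 to 43.6 M, with a median of 18.5 M. Values in brackets are log2 fold changes ± standard error, and levels are means ± SD in counts per M counts (CPM), with n = 7 per side unless another n is given. This standard error was derived from the test, as the size of the change over the square root of its quasi-likelihood F, and is approximate. A gene rose, fell or differed where edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Gene lists were tested with camera, and "adjusted over the list alone" marks counts of members whose p-values were adjusted within their list.

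The first question was what obstruction changed in PT by day 5. The injury marker Havcr1, kidney injury molecule 1, rose (7.29 ± 0.27, 1920 ± 286 against 12.5 ± 3.24 CPM), as did Vcam1, an adhesion molecule for leukocytes (7.69 ± 0.24, 638 ± 92.6 against 3.05 ± 0.947 CPM), Krt20, a keratin (6.72 ± 0.55), Lcn2, an iron-carrier binding lipocalin (4.23 ± 0.39), and Spp1, osteopontin (5.08 ± 0.28, 57600 ± 17800 against 2240 ± 2060 CPM). Transporters of the tubule fell: the phosphate carrier Slc34a1 (-2.64 ± 0.24, 624 ± 144 against 3880 ± 416 CPM), the endocytic receptor Lrp2 (-1.95 ± 0.23), the glucose carrier Slc5a2 (-2.82 ± 0.25) and the organic anion carrier Slc22a6 (-3.06 ± 0.28). The chemokines Ccl2 (6.0 ± 0.27, 64.8 ± 17.9 against 1.13 ± 1.01 CPM) and Cxcl1 (6.90 ± 0.48), the macrophage growth factors Csf1 (3.84 ± 0.31) and Il34 (3.02 ± 0.25), and the cell cycle inhibitor Cdkn1a (1.51 ± 0.31) rose. The Il34 value averages a rise in females and a change in males that missed the 2-fold minimum. C1qa, a macrophage marker, and Col1a1, a fibroblast collagen, rose as well (2.91 ± 0.42 and 3.19 ± 0.26).

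In PT at day 5, 4572 of 14932 tested genes changed, 2724 upward and 1848 downward. With library size as the only scaling, 83.2% of the called genes were higher against 59.6% with composition factors, and the median of all genes moved by 0.471 (log2). Among genes with a mean of at least 5 CPM in 1 sex on 1 side and without overlap between libraries of the sides within a sex, the largest rises were those of Steap4, a metalloreductase (420-fold higher, counting interval 75 to 16600), Serpina10, a protease inhibitor (7.80 ± 0.28), Timp1, an inhibitor of metalloproteinases (7.72 ± 0.29), Vcam1, Pik3r5, a subunit of a phosphoinositide kinase (7.52 ± 0.61), and the transcription factor Runx1 (7.46 ± 0.26). The largest falls were those of Pvalb, parvalbumin (-6.11 ± 0.62), Ttr, transthyretin (-5.86 ± 0.60), the cytochrome P450 genes Cyp4b1-ps2 and Cyp2d12 (-6.37 ± 1.11 and -5.63 ± 0.64, close copies of these genes make their read assignment uncertain), Gm4208 (-5.75 ± 1.00) and the noncoding Gm11513 (-7.78 ± 0.48).

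Tubule function lists fell in PT at day 5. Among PT solute carriers 23 of 28 tested members fell and 1 rose (23 and 1 adjusted over the list alone, median -1.82). Slc22a8 (-4.30 ± 0.47) and Slc34a3 (-3.75 ± 0.38) fell and Slc13a1, a sulfate carrier, rose (1.04 ± 0.20). Of the gluconeogenesis and PT metabolism list 17 of 21 fell and 1 rose (17 and 1 adjusted over the list alone, median -2.17). The phosphatase G6pc (-3.91 ± 0.25) and Hpd (-3.76 ± 0.63) fell and Cyp27b1, the vitamin D 1-hydroxylase, rose (2.61 ± 0.55). Fatty acid oxidation lost 21 of 30 members (21 adjusted over the list alone, median -1.34), with Acaa2 (-2.98 ± 0.22) and Acsm2 (-2.35 ± 0.23) among them. The respiratory chain lost 19 of 30 (20 adjusted over the list alone, median -1.16, camera adjusted p = 4.12e-10, adjusted p = 0.0763 with an estimated correlation), with Atp5b (-1.5 ± 0.22) and Ndufa10 (-1.61 ± 0.32). Markers of other segments fell too. The loop of Henle and distal convoluted tubule list lost 8 of 16, with 1 higher (8 and 1 adjusted over the list alone, median -1.21, camera adjusted p = 0.000925, adjusted p = 0.215 with an estimated correlation). The calcium binder Calb1 fell (-3.68 ± 0.31) and the magnesium channel Trpm6 rose (1.96 ± 0.31). The collecting duct list lost 6 of 13 (7 adjusted over the list alone, median -1.10, camera adjusted p = 0.011, adjusted p = 0.235 with an estimated correlation), with the water channel Aqp3 (-3.82 ± 0.33) and Rhcg (-2.13 ± 0.31).

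Injury and inflammation lists rose in the same libraries. The tubule injury and repair list gained 25 of 32 members (25 adjusted over the list alone, median 4.05). Chemokines, cytokines and adhesion gained 22 of 26, with 1 lower (22 and 1 adjusted over the list alone, median 3.81). The neutrophil attractant Cxcl2 rose (7.36 ± 0.44), while Cxcl12 fell (-2.33 ± 0.51). The NF-kB pathway list gained 18 of 20 (18 adjusted over the list alone, median 3.01), with Traf1 (7.14 ± 0.30) and Cd40 (5.03 ± 0.34). Immediate early genes gained 16 of 19 (16 adjusted over the list alone, median 3.11), with Egr1 (6.41 ± 0.42) and Klf4 (5.21 ± 0.37). Complement and acute phase genes gained 16 of 19, with 1 lower (16 and 1 adjusted over the list alone, median 3.47). C3 (6.34 ± 0.23) and ceruloplasmin, Cp (6.36 ± 0.29), rose. Profibrotic secreted factors gained 20 of 25, with 3 lower (20 and 3 adjusted over the list alone, median 2.35). Endothelin 1, Edn1, rose (6.60 ± 0.50), and epidermal growth factor, Egf, and Shh fell (-3.66 ± 0.39 and at least 4.22-fold lower). Camera called these 6 lists with the preset and with an estimated correlation.

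Antigen presentation and interferon lists rose under the preset correlation alone. Class II genes gained 6 of 7 (6 adjusted over the list alone, median 3.98, camera adjusted p = 3.65e-05, adjusted p = 0.133 with an estimated correlation). The invariant chain Cd74 (4.57 ± 0.37, 2110 ± 641 against 93.1 ± 52.7 CPM) and H2-Eb1 (4.55 ± 0.43) rose. The interferon response gained 20 of 26 with 1 lower (20 and 1 adjusted over the list alone, median 2.06, camera adjusted p = 2.21e-08, adjusted p = 0.0763 with an estimated correlation). The GTPases Gbp2 (4.84 ± 0.47) and Gbp3 (3.63 ± 0.50) rose and Cmpk2 fell (-1.41 ± 0.18). Camera called none of 3 further lists. In the p53 and DNA damage list 8 of 18 rose (8 adjusted over the list alone, camera adjusted p = 0.08, Btg2 3.11 ± 0.30, Bbc3 2.88 ± 0.39). In the cell cycle list 2 of 29 rose (2 adjusted over the list alone, camera adjusted p = 0.306, Ccne1 1.64 ± 0.53, Mcm3 1.42 ± 0.21). In the ATF4 and unfolded protein list 7 rose and 4 fell of 20 (7 and 4 adjusted over the list alone, camera adjusted p = 0.306, Atf3 4.34 ± 0.39, Asns 3.63 ± 0.24, Psat1 -1.95 ± 0.21, Sdf2l1 -1.19 ± 0.25).

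Markers of other cells were also present in PT. Macrophage markers rose in 19 of 20 members (19 adjusted over the list alone, median 2.86), with Cd14 (5.23 ± 0.34) and Cd68 (4.03 ± 0.39). Fibroblast markers rose in 18 of 19 (18 adjusted over the list alone, median 2.40), with Mfap5 (41.9-fold higher, counting interval 7.16 to 1690) and Postn (25.9-fold higher, counting interval 4.29 to 1060). Lymphocyte markers rose in 3 of 3 tested members (3 adjusted over the list alone, median 3.13), with Lck (5.10 ± 0.40) and Cd3g (3.13 ± 0.61). That list holds 17 genes, and the others were too low in PT to be tested. Endothelial markers rose in 8 of 15 and fell in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.08). Cdh5 (1.82 ± 0.49) and Eng (1.28 ± 0.27) rose and the receptor Kdr fell (-1.07 ± 0.34). Podocyte markers rose in 2 of 12 and fell in 1 (2 and 1 adjusted over the list alone, median -0.20, mean 0.17, camera adjusted p = 0.916). Wt1 (2.13 ± 0.30) and Synpo (1.77 ± 0.19) rose. None of 6 erythrocyte genes changed (0 adjusted over the list alone).

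Of 741 tested long noncoding RNAs 292 changed, 136 upward and 156 downward. Gm14005 (109-fold higher, counting interval 19.2 to 4330), D630011A20Rik (6.19 ± 0.29) and Gm15867 (67.3-fold higher, counting interval 18.3 to 561) rose most. Gm11513, Dtnbos (at least 8.06-fold lower) and C430042M11Rik (at least 8.78-fold lower) fell most. Of the fixed list of named long noncoding RNAs 5 of 21 rose (5 adjusted over the list alone, camera adjusted p = 0.306), among them the small nucleolar RNA hosts Snhg5 (1.84 ± 0.20) and Snhg6 (1.75 ± 0.28). D630011A20Rik overlaps Spaca7 on the opposite strand, Gm15867 Sertad4, Gm11513 Pdk2, Dtnbos Dtnb, and Gm14005 the genes Gm14009, Gm14010 and Gm29010, with Gm14012 on its own strand. Since the counting by strand was not stated, reads of these overlapping genes cannot be told apart.

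**Figure D1:**
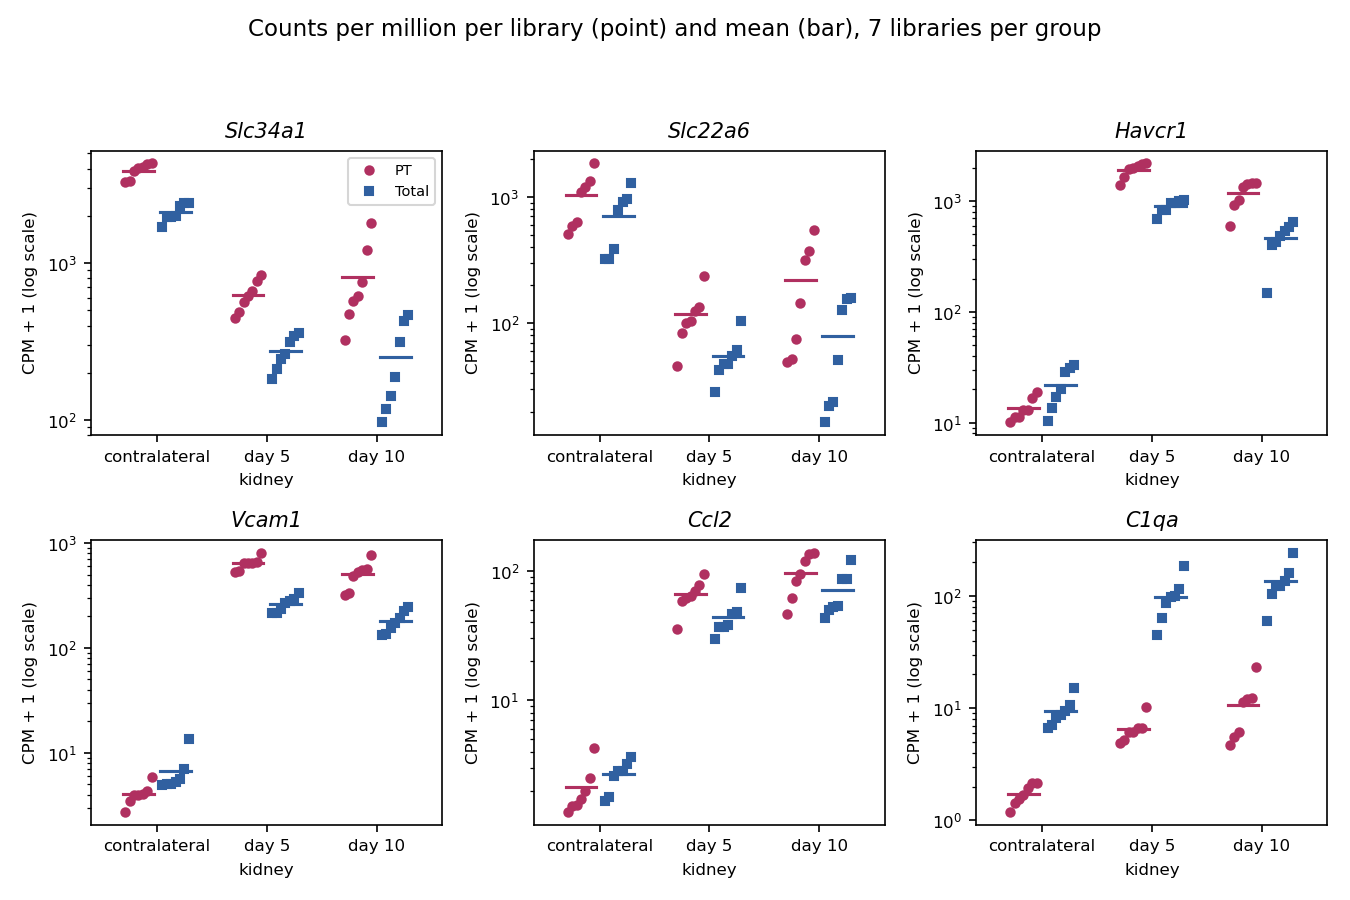
CPM + 1 on a log axis for 6 genes in each PT and Total library of contralateral, day 5 and day 10 kidneys; points are libraries and bars means, n = 7 per group. In PT at day 5 Havcr1 stood at 1920 ± 286 against 12.5 ± 3.24 CPM in contralateral kidneys.

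At day 10 the same 16 marker genes changed in PT in the same directions. Havcr1 (6.54 ± 0.26, 1180 ± 338 against 12.5 ± 3.24 CPM), Vcam1 (7.34 ± 0.24, 506 ± 151 against 3.05 ± 0.947 CPM), Krt20 (6.18 ± 0.54), Lcn2 (6.04 ± 0.41) and Spp1 (4.22 ± 0.27) rose. Slc34a1 (-2.48 ± 0.23, 821 ± 512 against 3880 ± 416 CPM), Lrp2 (-1.92 ± 0.23), Slc5a2 (-2.41 ± 0.24) and Slc22a6 (-2.69 ± 0.28) fell. Ccl2 (6.51 ± 0.28), Cxcl1 (6.32 ± 0.47), Il34 (3.63 ± 0.26), Csf1 (4.17 ± 0.32), Cdkn1a (1.58 ± 0.31), C1qa (3.70 ± 0.42, 9.75 ± 6.39 against 0.735 ± 0.366 CPM) and Col1a1 (3.73 ± 0.26) rose.

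In PT at day 10, 4733 of 14932 genes changed, 2943 upward and 1790 downward. Library size as the only scaling made 82.9% of the calls higher against 62.2% and moved the median of all genes by 0.438. The largest rises were those of Anxa8, an annexin (240-fold higher, counting interval 81.9 to 1170), Iqsec3 (at least 18.7-fold higher), the neutrophil chemokine Cxcl5 (8.36 ± 0.45), Rgs4, a regulator of G protein signalling (7.60 ± 0.52), Serpina10 (7.59 ± 0.28) and Runx1 (7.35 ± 0.26). The largest falls were those of Gm11513 (-6.14 ± 0.38), Pvalb (-5.93 ± 0.58), the cadherin Fat2 (-5.09 ± 0.50), Ttr (-5.00 ± 0.57), Gm13412 (-4.78 ± 0.60) and Bhmt, which methylates homocysteine (-4.74 ± 0.62). Gm27217 (at least 6.18-fold higher), Gm14005 (147-fold higher, counting interval 26 to 5820) and 2810468N07Rik (122-fold higher, counting interval 21.7 to 4860) were the long noncoding RNAs that rose most, and Gm11513, Dtnbos (97.4-fold lower, counting interval 26.5 to 811) and Ctcflos (-5.33 ± 1.03) those that fell most, of 271 that changed among 741. Strand again leaves 2810468N07Rik and Sox8, and Ctcflos and Ctcfl, unresolved.

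The tubule injury and repair list gained 28 of 32 members in PT at day 10 (28 adjusted over the list alone, median 4.24), with the hyaluronan receptor Cd44 (7.25 ± 0.36). Chemokines gained 22 of 26 with 1 lower (22 and 1 adjusted over the list alone, median 4.59). Class II genes gained 7 of 7 (7 adjusted over the list alone, median 4.74, camera adjusted p = 1.75e-05, adjusted p = 0.117 with an estimated correlation). The interferon response gained 21 of 26 with 1 lower (21 and 1 adjusted over the list alone, median 2.26, adjusted p = 0.061 with an estimated correlation). Solute carriers lost 23 of 28 (23 adjusted over the list alone, median -1.75) and the gluconeogenesis list 18 of 21 with 1 higher (18 and 1 adjusted over the list alone, median -1.87). Fatty acid oxidation lost 20 of 30 (20 adjusted over the list alone, median -1.28) and the respiratory chain 21 of 30 (21 adjusted over the list alone, median -1.12, adjusted p = 0.0797 with an estimated correlation). Cell cycle genes gained 10 of 29 (10 adjusted over the list alone, median 0.86, camera adjusted p = 0.00462, adjusted p = 0.473 with an estimated correlation). Beside these, macrophage markers gained 19 of 20 (19 adjusted over the list alone, median 3.52), fibroblast markers 18 of 19 (18 adjusted over the list alone, median 3.03) and endothelial markers 10 of 15 (11 adjusted over the list alone, camera adjusted p = 0.0091, adjusted p = 0.312 with an estimated correlation). The podocyte list gained 3 of 12 (3 adjusted over the list alone), Wt1 standing at 20 ± 8.43 against 2.8 ± 1.22 CPM. Of the erythrocyte genes 3 of 6 rose (3 adjusted over the list alone), with Hba-a1 (1.74 ± 0.56) and Hbb-bs (1.67 ± 0.57). In the PT libraries of low Lars2 alone, 3 at day 10 against 2 contralateral with 1 per sex, these 2 values were -0.32 and -0.58 and passed no test, and in those of high Lars2, 4 against 5, they were 2.25 and 2.51.

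Day 10 and day 5 were then compared within PT. Lcn2 rose further (1.81 ± 0.32, 46.3 ± 28.6 against 12.4 ± 4.34 CPM) and was the only marker gene to pass, since Havcr1 (-0.75 ± 0.20, adjusted p = 0.101 by edgeR's quasi-likelihood test) and Spp1 (-0.85 ± 0.24) did not. Against contralateral kidneys Lcn2 rose less in PT than in Total (-2.88 ± 0.52 at day 5, -1.65 ± 0.51 at day 10). RNA of other cells therefore stays open as its source. Rises were largest for Anxa8 (4.52 ± 0.70), the transcription factor Sox8 (2.19 ± 0.33), Bst1 (2.21 ± 0.46), Anxa1 (2.03 ± 0.28), Cald1, an actin binder (1.99 ± 0.29), and Adgra1 (1.93 ± 0.29). Sprr1a (-1.76 ± 0.31) and the glutathione transferase Gsta2 (-1.47 ± 0.32) were the falls that met the naming rule. In all 66 of 14932 genes changed by edgeR, 63 upward and 3 downward. With 1 library left out 23 to 93 did. DESeq2 called 192, and 1573 lay under an unadjusted p of 0.05. No long noncoding RNA of 741 passed in edgeR, and 7 did in DESeq2. In the PT libraries of high Lars2 alone no gene passed, and in those of low Lars2 89 did.

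Macrophage markers stood higher at day 10 than at day 5 as a list (median 0.64, 2 of 20 rose, 2 adjusted over the list alone), with lysozyme, Lyz2 (1.06 ± 0.21), and Ms4a7 (1.88 ± 0.37). Camera's calls for fibroblast markers (median 0.54, adjusted p = 1.99e-07) and cell cycle genes (median 0.68, adjusted p = 1.01e-07) ended with an estimated correlation (adjusted p = 0.181 with an estimated correlation and adjusted p = 0.358 with an estimated correlation). Krt19, a keratin of injured tubules (1.86 ± 0.29), and Tnfaip2 (1.21 ± 0.23) rose on the injury and NF-kB lists.

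Each sex was also compared with its own contralateral kidneys, 4 libraries per side in males and 3 per side in females. At day 5 Havcr1 rose in males (7.05 ± 0.34) and in females (7.52 ± 0.40), and Slc34a1 fell in both (-2.68 ± 0.31 and -2.59 ± 0.35). Il34 rose in females (5.24 ± 0.42, 125 ± 16.6 against 3.3 ± 0.227 CPM) and missed the 2-fold minimum in males (0.80 ± 0.30, 153 ± 13.7 against 86.9 ± 41.8 CPM). The androgen-dependent Cyp4a12a rose in females (4.31 ± 0.48) and fell in males (-1.64 ± 0.37). Close copies leave its read assignment uncertain. Male rises were largest for Wfdc18 (478-fold higher, counting interval 132 to 3960), Sox11 (8.04 ± 1.09), Timp1 (7.49 ± 0.38), Sfn (7.46 ± 0.74), Cxcl5 (286-fold higher, counting interval 79 to 2370) and Vcam1 (7.86 ± 0.31). Cyp4b1-ps2 (-6.47 ± 1.27), Ttr (-5.77 ± 0.75), Pde6a (-5.63 ± 0.68), Fat2 (-5.21 ± 0.61), BC002163 (-5.14 ± 1.20) and Pik3c2g (-4.79 ± 0.56) were the largest male falls. In females Pik3r5 (at least 27-fold higher), Serpina10 (8.63 ± 0.43), Timp1 (7.95 ± 0.43), Steap4 (271-fold higher, counting interval 48.2 to 10700), Sox9 (7.72 ± 0.84) and Runx1 (7.58 ± 0.39) rose most. Gm11513 (at least 29.6-fold lower), Pvalb (256-fold lower, counting interval 45.6 to 10200), Bhmt (-6.75 ± 1.01), Cyp2d12 (-6.47 ± 1.00), Gm13412 (-6.41 ± 1.00) and Gfra1 (-6.26 ± 2.06) fell most.

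At day 10 male rises were largest for Wfdc18 (357-fold higher, counting interval 98.5 to 2950), the hexokinase Hk2 (367-fold higher, counting interval 65.5 to 14500), Sox11 (8.06 ± 1.09), Cxcl5 (325-fold higher, counting interval 89.8 to 2690), Rgs4 (7.63 ± 0.70) and the kinase Mapk11 (7.40 ± 0.42). Male falls were largest for Pde6a (-4.86 ± 0.63), Rxrg (-4.0 ± 0.64), Ttr (-3.97 ± 0.69), Fat2 (-3.76 ± 0.55), Calb1 (-3.60 ± 0.39) and Snx31 (-3.56 ± 0.51). In females Anxa8 (at least 57.3-fold higher, at least 27.4-fold without replicate 3), Iqsec3 (at least 24.8-fold higher), Cxcl5 (439-fold higher, counting interval 121 to 3630), Serpina10 (8.36 ± 0.43), follistatin, Fst (312-fold higher, counting interval 107 to 1520), and Runx1 (7.68 ± 0.39) rose most at day 10. In the same comparison Gm13412 (-6.83 ± 1.00), Bhmt (-6.80 ± 1.00), Gm11513 (116-fold lower, counting interval 39.4 to 568), Fat2 (-6.42 ± 0.85), Ttr (-6.03 ± 0.90) and albumin, Alb (-5.81 ± 0.79), fell most.

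Counts of changed genes per sex were 4217 in males and 3972 in females at day 5, and 3901 and 4566 at day 10. With the clock score the female count at day 5 was 2498, 1607 of them shared, and the male count 4169, 3907 of them shared. At day 5, 1778 genes rose and 1146 fell in both sexes, against 379 and 197 for independent lists, and 10 passed in opposite directions. At day 10 the numbers were 2131 and 1091 against 462 and 166, with 4 opposite. With library size as the only scaling the share of higher genes rose at day 5 to 85.3% from 58.8% in males and to 78.5% from 57.4% in females, and at day 10 to 86.7% from 66.9% and to 79.6% from 57.9%. The medians of all genes moved by 0.522, 0.42, 0.418 and 0.463 in that order, and by 0.101 in females at day 10 with upper-quartile factors.

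Total libraries were compared in the same way. At day 5 Lcn2 rose most among the marker genes (7.08 ± 0.32, 181 ± 91.7 against 1.31 ± 0.521 CPM). Havcr1 (5.42 ± 0.26, 902 ± 123 against 21 ± 8.97 CPM), Vcam1 (5.50 ± 0.26), Krt20 (5.97 ± 0.55), Spp1 (3.98 ± 0.27), Ccl2 (4.68 ± 0.30), C1qa (3.52 ± 0.29) and Col1a1 (3.90 ± 0.25) rose, and Slc34a1 (-2.95 ± 0.21), Slc5a2 (-2.96 ± 0.21) and Slc22a6 (-3.54 ± 0.25) fell. The largest rises were those of Ear2, an eosinophil ribonuclease (386-fold higher, counting interval 107 to 3190), the interleukin Il1f6 (8.47 ± 0.56), Arhgap36 (8.20 ± 0.44), the chemokine Cxcl17 (7.93 ± 0.43), Adgra1 (7.75 ± 0.50) and Lcn2. Pvalb (-9.35 ± 0.71), Gm28438 (-8.38 ± 1.61), Fat2 (-6.10 ± 0.45), Cyp4b1-ps2 (-5.97 ± 1.08), Cyp2d12 (-5.85 ± 0.52) and Bhmt (-5.79 ± 0.40) fell most. 5453 of 16782 genes changed, 3220 upward and 2233 downward. Macrophage markers rose in 22 of 22 (22 adjusted over the list alone, median 3.26, camera adjusted p = 5.09e-14, adjusted p = 0.0504 with an estimated correlation). Fibroblast markers rose in 19 of 21 (19 adjusted over the list alone, median 2.66, adjusted p = 0.0504 with an estimated correlation) and lymphocyte markers in 15 of 17 (15 adjusted over the list alone, median 2.85, adjusted p = 0.0778 with an estimated correlation). The injury list rose in 28 of 32 (28 adjusted over the list alone, median 2.72). Of 1135 long noncoding RNAs 410 changed. Gm15867 (51.6-fold higher, counting interval 17.4 to 252), 4932411K12Rik (4.91 ± 0.64) and D630011A20Rik (4.81 ± 0.33) rose most, and Gm12326 (-4.83 ± 0.48), Gm12962 (-4.72 ± 0.48) and Dtnbos (-4.66 ± 0.36) fell most. 4932411K12Rik overlaps Gm2534 on its own strand and Gm36994 on the opposite one, with the same limit.

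At day 10 Retnla, a marker of alternatively activated macrophages, was among the largest rises in Total (10.13 ± 0.84, 26.3 ± 16.9 against 0.0436 ± 0.115 CPM), with all contralateral counts in 1 library and at least 144-fold higher without it. Others were Ear2 (629-fold higher, counting interval 174 to 5200), the metalloproteinase Mmp7 (at least 17.9-fold higher, at least 11.8-fold without female day 10 replicate 3), surfactant protein D, Sftpd (450-fold higher, counting interval 80.5 to 17800), Rgs16 (243-fold higher, counting interval 66.8 to 2010) and Arhgap36 (8.13 ± 0.44). Pvalb (-6.84 ± 0.59), Bhmt (-6.30 ± 0.44), Larp1b (-5.44 ± 0.23), Alb (-5.25 ± 0.44), Fat2 (-5.15 ± 0.42) and Cyp2d12 (-5.05 ± 0.49) fell most. 5814 genes changed, 3506 upward and 2308 downward, and with the replicate number as a block, which pairs these contralateral and day 10 libraries, 5839 did. Lymphocyte markers rose in 16 of 17 (16 adjusted over the list alone, median 3.10, adjusted p = 0.0819 with an estimated correlation). Collecting duct markers fell in 12 of 16 with 1 higher (12 and 1 adjusted over the list alone, median -1.67, adjusted p = 0.051 with an estimated correlation) and loop and distal tubule markers in 11 of 16 (11 adjusted over the list alone, median -1.47, adjusted p = 0.051 with an estimated correlation). With library size as the only scaling 80.4% of the Total calls were higher at day 5 against 59.1%, and 76% against 60.3% at day 10. The medians of all genes moved by 0.444 and 0.361, and by 0.134 and 0.137 with upper-quartile factors.

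Between day 5 and day 10 in Total, lysozyme Lyz1 (4.15 ± 0.43, 6.62 ± 4.01 against 0.361 ± 0.187 CPM), Retnla (3.74 ± 0.48), the B cell attractant Cxcl13 (3.53 ± 0.56), Npr3 (2.08 ± 0.29), macrophage elastase, Mmp12 (1.93 ± 0.21), and Ccl22 (1.67 ± 0.33) rose most. Xirp2 (-1.69 ± 0.31), Gsta2 (-1.41 ± 0.31), Hmga1 (-1.29 ± 0.26), Cyp4a12b (-1.29 ± 0.20) and Prrg4 (-1.05 ± 0.24) fell. 66 genes changed by edgeR, 59 upward and 7 downward, 161 by DESeq2 and 17 to 95 with 1 library left out. Without the 3 Total libraries of lowest Lars2 14 changed by edgeR. No long noncoding RNA of 1135 passed in edgeR, and 8 did in DESeq2.

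**Figure D2:**
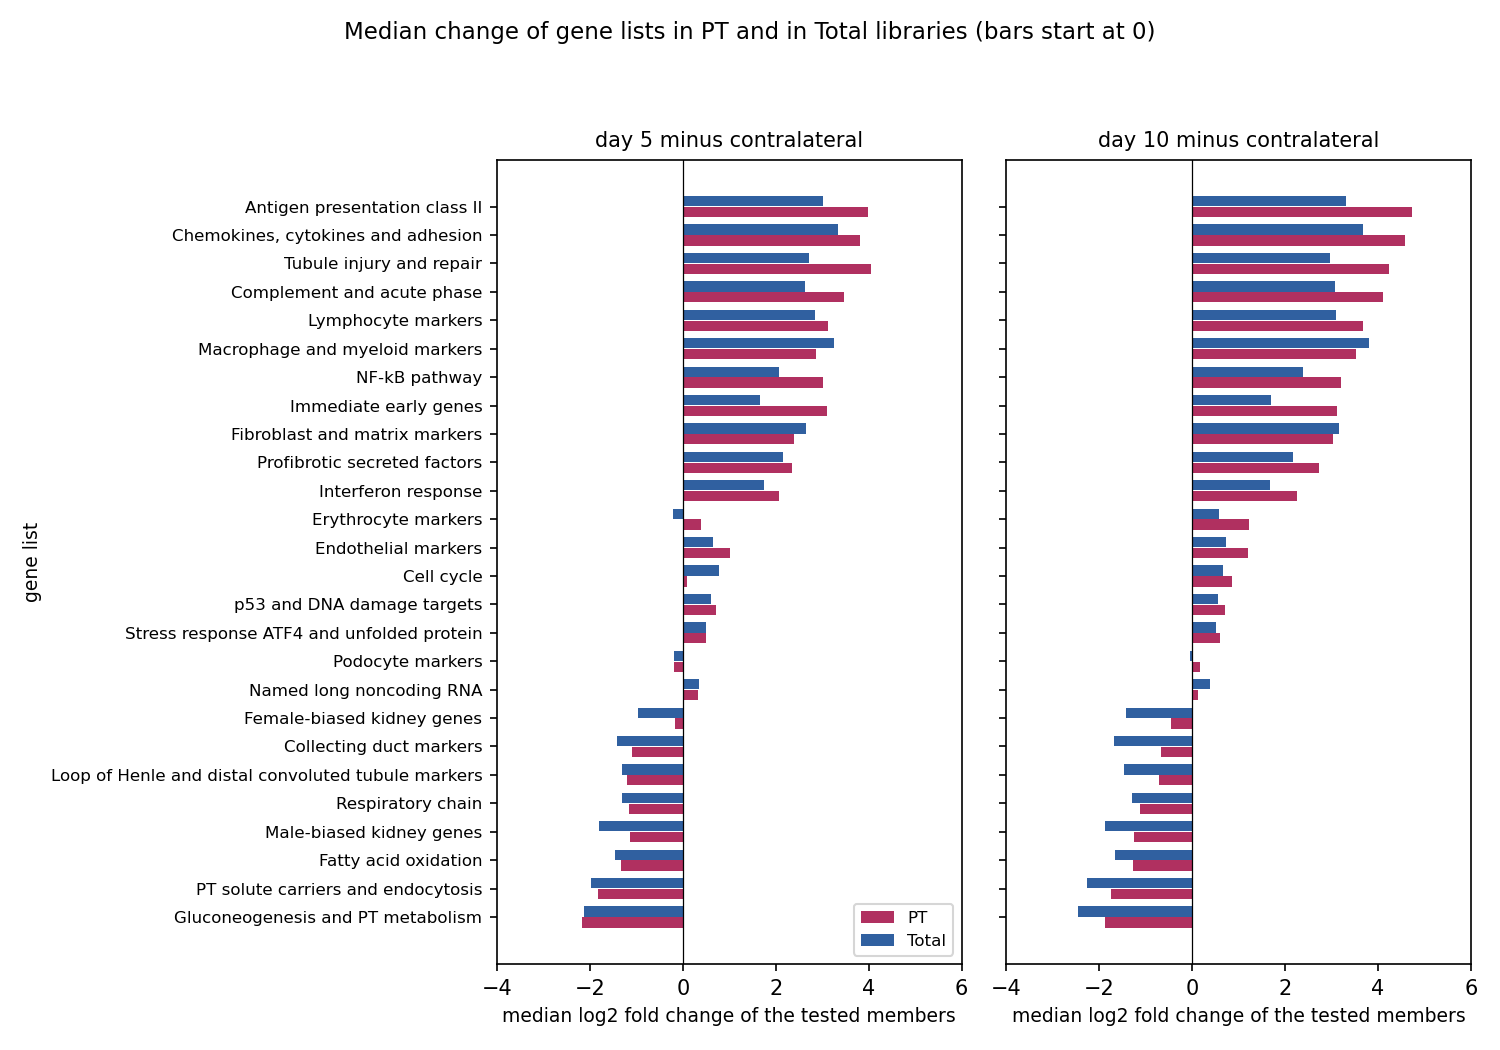
Median log2 fold change of the tested members of 26 gene lists at day 5 and day 10 of obstruction against contralateral kidneys, in PT and in Total libraries; bars start at 0 and n = 7 libraries per side. Macrophage markers had a median of 3.52 in PT and 3.81 in Total at day 10. The tested members of a list could differ between PT and Total.

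PT was next set against Total. In contralateral kidneys markers of other cells stood lower in PT: the macrophage gene C1qa (-3.48 ± 0.39), Col1a1 (-3.85 ± 0.28), the endothelial Pecam1 (-3.98 ± 0.24), uromodulin, Umod (-4.37 ± 0.22), the distal tubule carrier Slc12a3 (-4.87 ± 0.27, 5.8 ± 2.71 against 171 ± 86.9 CPM), the collecting duct water channel Aqp2 (-2.21 ± 0.55, 4.89 ± 3.92 against 22.3 ± 9.41 CPM) and haemoglobin, Hbb-bs (-4.27 ± 0.68). Slc34a1 (0.91 ± 0.21) and Slc5a2 (0.99 ± 0.22) stood just under the 2-fold minimum, and Lrp2 (-0.57 ± 0.20) did not pass. The highest in PT over Total were superoxide dismutase, Sod1 (2.08 ± 0.61), Spink1 (1.60 ± 0.34), Msrb1 (1.52 ± 0.21), Chchd10 (1.5 ± 0.30), Stra6 (1.46 ± 0.35) and Akr7a5 (1.45 ± 0.25). Mitochondrial transcripts were lowest, with mt-Rnr2 (-7.28 ± 0.37), mt-Rnr1 (-7.23 ± 0.37), mt-Tp (-7.06 ± 0.45), mt-Nd1 (-7.00 ± 0.30), mt-Nd2 (-6.93 ± 0.34) and mt-Tq (-6.82 ± 0.57), and so was the nuclear RNA Malat1 (-6.16 ± 0.38). All 21 fibroblast (21 adjusted over the list alone, median -3.91) and all 22 macrophage members (22 adjusted over the list alone, median -3.73) stood lower. So did 14 of 15 endothelial (14 adjusted over the list alone), 15 of 16 loop and distal tubule (15 adjusted over the list alone, median -4.33) and 15 of 16 collecting duct members (15 adjusted over the list alone). Podocyte markers were lower in 11 of 12 (11 adjusted over the list alone, adjusted p = 0.154 with an estimated correlation), lymphocyte markers in 15 of 17 (16 adjusted over the list alone, adjusted p = 0.154 with an estimated correlation) and erythrocyte genes in 5 of 7 (5 adjusted over the list alone).

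4123 of 17110 genes differed in contralateral kidneys, 198 higher in PT and 3925 lower, and 4155 with the kidney as a block. With library size as the only scaling 29 were higher and 4698 lower, with RLE factors 266 and 3841, and the median of all genes moved by -0.306 with library size only. At day 5 Slc34a1 (1.20 ± 0.21) and Slc5a2 (1.10 ± 0.22) stood higher in PT, and 16 of 28 solute carriers did (16 adjusted over the list alone, median 1.05, camera adjusted p = 1.33e-06, adjusted p = 0.206 with an estimated correlation). The xenobiotic receptor Nr1i2 (1.88 ± 0.17), Serpina7 (1.93 ± 0.38), Spink1 (1.93 ± 0.35) and Acot1 (1.72 ± 0.19) also stood higher. C1qa (-4.12 ± 0.35), Col1a1 (-4.56 ± 0.26), Pecam1 (-3.61 ± 0.22) and Umod (-4.08 ± 0.22) stood lower, and mt-Tp (-7.11 ± 0.49), mt-Rnr2 (-6.88 ± 0.37), the microRNA host Mir143hg (351-fold lower, counting interval 96.7 to 2900) and Gm24265 (at least 17.5-fold lower, at least 7.76-fold without female Total replicate 3 at 12.6 CPM) lowest. 688 genes were higher and 4077 lower in PT, against 229 and 4609 under library size only, with a median shift of -0.258, and 490 and 4229 under upper-quartile factors. At day 10 the differences were Slc34a1 (1.80 ± 0.21, 821 ± 512 against 249 ± 153 CPM), Slc5a2 (1.77 ± 0.22), the isocitrate dehydrogenase Idh1 (2.16 ± 0.21), the plasma glutathione peroxidase Gpx3 (2.09 ± 0.24), Cyp4a12b (2.11 ± 0.28), Depdc1b (2.19 ± 0.25), complement factor B, Cfb (2.13 ± 0.35), and Gm10845 (2.45 ± 0.25). 20 of 28 solute carriers (20 adjusted over the list alone, median 1.4, adjusted p = 0.116 with an estimated correlation), 16 of 21 gluconeogenesis (17 adjusted over the list alone, median 1.47, adjusted p = 0.0948 with an estimated correlation) and 13 of 30 fatty acid oxidation members (13 adjusted over the list alone, median 0.97, adjusted p = 0.047 with an estimated correlation) stood higher in PT at day 10. C1qa (-3.78 ± 0.34, 9.75 ± 6.39 against 134 ± 56.3 CPM), Col1a1 (-4.40 ± 0.26), Umod (-3.47 ± 0.21) and Slc12a3 (-3.95 ± 0.26) stood lower, as did mt-Rnr2 (-7.47 ± 0.38) and mt-Nd1 (-6.84 ± 0.29). 1209 genes were higher and 3942 lower, 5231 in all with the kidney as a block against 5151 without. Library size as the only scaling left 10.6% of the calls higher against 23.5%. The median of all genes moved by -0.262 with library size only, -0.129 with upper-quartile and -0.104 with RLE factors.

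Whether obstruction changed PT and Total by different amounts was tested as an interaction, PT change minus Total change. At day 5 Havcr1 (1.84 ± 0.31), Vcam1 (2.17 ± 0.30), Csf1 (1.68 ± 0.36) and Ccl2 (1.30 ± 0.38) rose more in PT, and Lcn2 rose less (-2.88 ± 0.52). C1qa (-0.64 ± 0.52) and Col1a1 (-0.72 ± 0.36) did not pass. Steap4 (5.74 ± 0.91), Rgs4 (4.73 ± 0.61), Rasd2 (4.20 ± 0.42), Mapk11 (4.08 ± 0.38) and the choline carrier-like Slc44a3 (3.98 ± 0.37) rose more in PT, as did Pik3r5 (4.17 ± 0.81, -0.16 under limma on log2 RPKM). Ear2 (-6.48 ± 1.42), Arhgap36 (-5.55 ± 0.85), Slco2b1 (-4.04 ± 0.34), the guanylate cyclase subunits Gucy1a3 (-3.95 ± 0.29) and Gucy1b3 (-3.79 ± 0.38) and Plbd1 (-3.70 ± 0.29) changed less or downward in PT. Steap4 had 1 count in contralateral PT and Ear2 2 in contralateral Total, so their fitted sizes rest on the prior count. 730 of 17110 genes differed, 517 upward and 213 downward. NF-kB genes were higher in 7 of 20 (8 adjusted over the list alone, median 0.89) and immediate early genes in 8 of 19 (8 adjusted over the list alone, median 0.70, adjusted p = 0.0871 with an estimated correlation). Injury genes were higher in 12 with 3 lower of 32 (14 and 3 adjusted over the list alone, median 0.67, adjusted p = 0.309 with an estimated correlation). Markers of other segments and of podocytes also stood higher, among them Trpm6 (2.88 ± 0.37), Atp6v0d2 (1.03 ± 0.31), Wt1 (1.62 ± 0.36) and Synpo (1.11 ± 0.23). Aqp3 (-1.55 ± 0.36) and Tcf21 (-1.8 ± 0.29) of the same lists stood lower. Camera called lymphocyte markers lower as a list (median -0.24, camera adjusted p = 1.15e-08, adjusted p = 0.0471 with an estimated correlation), but 0 of 17 passed downward and 1 upward, Lck (1.99 ± 0.45, -0.82 under limma on log2 RPKM).

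At day 10 Havcr1 (2.14 ± 0.31), Vcam1 (2.39 ± 0.30), Csf1 (1.96 ± 0.36), Il34 (1.31 ± 0.33) and Spp1 (1.09 ± 0.34) rose more in PT and Lcn2 less (-1.65 ± 0.51). Anxa8 (5.29 ± 1.34, against 3 counts in contralateral PT, so that the fitted size rests on the prior count), Rgs4 (5.08 ± 0.60), Rasd2 (4.48 ± 0.42), Mapk11 (4.44 ± 0.38), Slc44a3 (4.26 ± 0.37) and Traf1 (4.15 ± 0.34) were highest. Ear2 (-6.50 ± 1.41), Sftpd (-5.32 ± 1.70), Arhgap36 (-4.45 ± 0.82), the collagen Col12a1 (-4.24 ± 0.32), the cationic amino acid carrier Slc7a2 (-3.93 ± 0.62) and Slco2b1 (-3.79 ± 0.33) were lowest. Ear2 and Sftpd had 2 and 1 counts in contralateral Total, which limits their sizes in the same way. 985 genes differed, 801 upward and 184 downward, and RLE factors moved the median of all genes by -0.148. Injury genes were higher in 16 of 32 with 2 lower (16 and 2 adjusted over the list alone, median 1.03, adjusted p = 0.0755 with an estimated correlation) and NF-kB genes in 8 of 20 (10 adjusted over the list alone, median 1.07). Beside these, loop and distal convoluted tubule markers were higher in 4 of 16 (4 adjusted over the list alone, median 0.91, adjusted p = 0.14 with an estimated correlation), with Trpm6 (3.91 ± 0.37) and Tmem72 (1.59 ± 0.27). Collecting duct markers were higher in 3 of 16 (3 adjusted over the list alone, median 0.42, adjusted p = 0.369 with an estimated correlation), with Atp6v0d2 (1.92 ± 0.30) and Foxi1 (1.45 ± 0.36), and podocyte markers in 2 of 12 with 1 lower (2 and 1 adjusted over the list alone, median 0.39), among them Wt1 (1.89 ± 0.36). Fibroblast markers had a median of -0.22 and a mean of 0.07 (camera downward, adjusted p = 0.00208, adjusted p = 0.369 with an estimated correlation).

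Females and males were compared within PT, 3 libraries against 4. In contralateral kidneys the androgen-regulated Kap (-5.85 ± 0.40, 178 ± 54.2 against 10100 ± 3830 CPM), the amino acid carrier Slc7a13 (-7.12 ± 0.53), the organic anion carrier Slco1a1 (-7.36 ± 0.54, 1.99 ± 1.04 against 318 ± 106 CPM), Cyp4b1 (-2.95 ± 0.39) and the Y-linked Ddx3y (-6.37 ± 0.54) stood lower in females. The prolactin receptor Prlr (5.12 ± 0.37, 168 ± 59.3 against 4.73 ± 2.12 CPM) and Cyp4a14 (5.09 ± 0.98) stood higher, while Akr1c18 (-2.48 ± 0.96) and Slc7a12 (1.08 ± 0.49) did not pass. Il34 stood lower in females (-4.73 ± 0.40, 3.3 ± 0.227 against 86.9 ± 41.8 CPM) and Spp1 higher (2.64 ± 0.34, 4310 ± 1170 against 684 ± 214 CPM). Xist, too low to be tested, was at least 1.91-fold higher in females, against 0 counts in males. Ugt1a2 (9.01 ± 0.79), the fatty acid binder Fabp1 (4.80 ± 0.57), Clic6 (4.75 ± 0.84) and Gsta4 (4.40 ± 0.45) were among the 6 highest in females. Gm15348 (252-fold lower, counting interval 45.1 to 9990), Y-linked Uty (-7.19 ± 0.44), Ctxn3 (-7.22 ± 1.08) and Cyp2j13 (-7.04 ± 0.39) were among the 6 lowest. Of long noncoding RNAs, 9230105E05Rik (322-fold higher, counting interval 57 to 12800) stood highest and Gm15563 (65.1-fold lower, counting interval 22.1 to 318) and Gm20713 (42.7-fold lower, counting interval 14.4 to 209) lowest after Gm15348. They overlap Hmga2, Usp3 and Gpc5 on the opposite strand, whose reads cannot be told apart from theirs. The male-biased list was lower in 12 of 17 (12 adjusted over the list alone, median -3.41). The female-biased list was higher in 6 and lower in 3 of 14 (7 and 5 adjusted over the list alone, camera adjusted p = 0.0773). 617 genes differed, 299 higher and 318 lower in females, against 403 with only the compared groups, 308 by limma on log2 RPKM and 235 with the clock score.

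**Figure D3:**
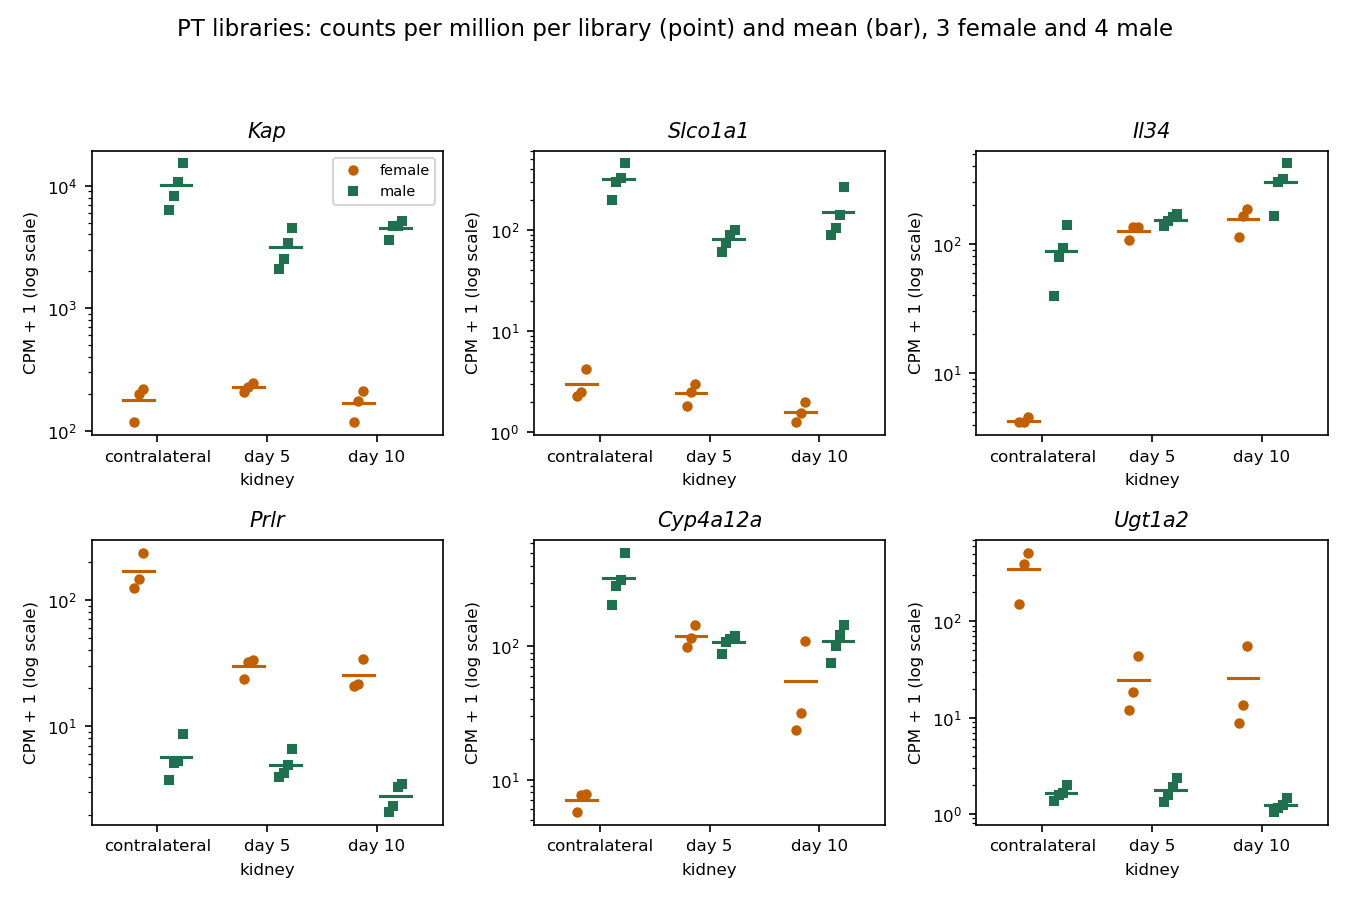
CPM + 1 on a log axis for 6 genes in each PT library of 3 females and 4 males per state; points are libraries and bars means. Il34 stood at 3.3 ± 0.227 against 86.9 ± 41.8 CPM in contralateral females against males.

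At day 5 of obstruction Ugt1a2 (4.88 ± 0.69), Prlr (2.87 ± 0.35), the growth factor Igf1 (2.20 ± 0.38), Pgm5 (3.36 ± 0.67), Akr1c19 (2.21 ± 0.28) and Mettl7a2 (2.08 ± 0.33) stood highest in females. Y-linked Eif2s3y (-7.85 ± 0.48), Kdm5d (227-fold lower, counting interval 62.7 to 1880), Ddx3y (-7.39 ± 0.59) and Uty (-6.89 ± 0.44), with Slc7a13 (-6.15 ± 0.53) and Slco1a1 (-5.79 ± 0.51), stood lowest. 127 genes differed, 41 higher and 86 lower, against 265 with only the compared groups, 241 by DESeq2 and 56 to 111 with 1 library left out. Library size as the only scaling left 22% of the calls higher against 32.3%. The male-biased list was lower in 9 of 17 (10 adjusted over the list alone, median -1.13). At day 10 Ugt1a2 (6.74 ± 0.79), Prlr (3.76 ± 0.37), Homer2 (2.69 ± 0.52), Dnajb3 (2.66 ± 0.41), Serpina1f (2.50 ± 0.46) and Akr1c20 (2.47 ± 0.35) were highest in females. Kdm5d (560-fold lower, counting interval 100 to 22100), apolipoprotein H, Apoh (441-fold lower, counting interval 78.8 to 17400), Slco1a1 (-7.91 ± 0.57), Uty (-7.51 ± 0.45), Eif2s3y (-7.27 ± 0.46) and Ddx3y (-7.24 ± 0.58) were lowest. In all 332 genes differed, 101 higher and 231 lower, against 98 with only the compared groups, 521 by DESeq2 and 149 to 465 with 1 library left out. The male-biased list was lower in 10 of 17 (13 adjusted over the list alone, median -3.51). Solute carriers were lower in 6 of 28 (7 adjusted over the list alone, median -0.22, adjusted p = 0.456 with an estimated correlation), with the urate carrier Slc22a12 (-2.82 ± 0.51) and Slc22a6 (-2.60 ± 0.40). Library size as the only scaling moved the median of all genes by 0.102.

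Sex differences in the response of PT were tested as an interaction, female change minus male change. At day 5 Il34 rose more in females (4.44 ± 0.49), with Ctxn3 (7.01 ± 1.27), Cyp4a12a (5.95 ± 0.60), the noncoding Gm15895 (5.08 ± 0.48), Crispld2 (4.99 ± 0.48) and the clock gene Npas2 (4.10 ± 0.77). Gm15895 overlaps Il34 on the opposite strand, so their reads cannot be told apart. The clock gene Ciart (-5.11 ± 0.92), Aldh1l2 (-4.40 ± 0.95), the inhibitor of differentiation Id1 (-3.63 ± 0.63), Xirp2 (-3.63 ± 0.81) and Kynu (-3.25 ± 0.42) moved the other way, as did the cadherin Cdh6 (-3.83 ± 0.82, 0.24 under limma on log2 RPKM). Kap (2.07 ± 0.44) and Prlr (-2.25 ± 0.49) differed too. 75 genes differed, 44 upward and 31 downward, against 12 with the clock score, 40 with library size only, 191 by DESeq2 and 22 without female day 5 replicate 1. Library size as the only scaling moved the median of all genes by -0.105. Of the male-biased list 3 of 17 passed upward (7 adjusted over the list alone, camera adjusted p = 2.18e-12, adjusted p = 0.089 with an estimated correlation). At day 10 Ctxn3 (6.80 ± 1.25), the sugar phosphate carrier Slc37a1 (5.85 ± 0.95), Cyp4a12a (4.72 ± 0.59), Gm15895 (4.50 ± 0.47), the steroid dehydrogenase Hsd11b1 (4.38 ± 0.78) and Il34 (3.74 ± 0.48) rose more in females. The bile acid conjugator Baat (-3.03 ± 0.58), Kynu (-2.65 ± 0.42), utrophin, Utrn (-2.32 ± 0.43), Cndp1 (-1.56 ± 0.32) and the long noncoding 9230105E05Rik (-5.62 ± 1.14) and Gm11788 (-6.67 ± 1.28) moved the other way. In all 31 genes differed, 24 upward and 7 downward, against 13 with only the compared groups, 100 by DESeq2 and 15 to 39 with 1 library left out. Slc37a1 had 2 counts in contralateral females, 9230105E05Rik 1 in contralateral males and Gm11788 0 in females at day 10, so their fitted sizes rest on the prior count. 9230105E05Rik overlaps Hmga2 and Gm11788 Slc25a10 on the opposite strand, with reads that cannot be told apart.

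Lists of sex-biased genes were also compared between obstructed and contralateral kidneys. At day 5 in PT of both sexes the male-biased list lost 10 of 17 and gained 2 (10 and 2 adjusted over the list alone, median -1.14, camera adjusted p = 0.00396, adjusted p = 0.264 with an estimated correlation). Acsm3 (-3.09 ± 0.49) and Cyp4b1 (-3.02 ± 0.27) fell and the diamine oxidase Aoc1 rose (6.92 ± 0.23). The female-biased list lost 5 and gained 2 of 14 (5 and 2 adjusted over the list alone, median -0.17, camera adjusted p = 0.33). Cyp2d12 and Slc22a7 (-3.18 ± 0.63) fell and the exporter Abcc3 (2.44 ± 0.48) and Bok (1.66 ± 0.54) rose. Of 4 sex chromosome genes none changed (0 adjusted over the list alone). Of 299 genes higher in contralateral females 16 differed the same way at day 5 and 42 at day 10, and of 318 higher in males 53 and 107. The interaction passed towards a smaller difference for 25 and 41 of these genes at day 5, and for 5 and 24 at day 10.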

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

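The tests of a constant share of other cells' RNA and of the sign of the clock genes were chosen only after the result was seen. The clock score and the library split were themselves added after clock genes and the split had been seen, with the bounds for their ratios written before those ratios were computed. The splits of the day 10 fraction by state result that kept contralateral and day 10 kidneys of one number together were added after the other splits had been seen. The other tests in this part were planned. Of 47 groups of 4 or 7 libraries tested for a level far from the rest, 6 held one, and chance flags about 1 in 20 groups. They were Ccl2 in female contralateral PT replicate 1 (3.26 CPM), Cd74 in male contralateral PT replicate 4 (204 CPM), C1qa in female day 10 PT replicate 3 (22.2 CPM), Retnla in male contralateral Total replicate 1 (0.305 CPM), Aqp2 in female contralateral Total replicate 3 (41.4 CPM) and the depth of male day 5 PT replicate 3 (17.6 M counts).

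Effects differed between days, fractions or sexes by a test of the difference itself (edgeR) for 66 genes between the days in PT and 66 in Total, 730 and 985 genes between fractions at day 5 and day 10, and 75 and 31 genes between the sexes. The named ones, in log2, were these. Day 10 minus day 5 in PT gave Lcn2 1.81, Anxa8 4.52, Sox8 2.19, Bst1 2.21, Anxa1 2.03, Cald1 1.99, Adgra1 1.93, Sprr1a -1.76, Gsta2 -1.47, Lyz2 1.06, Ms4a7 1.88, Krt19 1.86 and Tnfaip2 1.21. The same difference in Total gave Lyz1 4.15, Retnla 3.74, Cxcl13 3.53, Npr3 2.08, Mmp12 1.93, Ccl22 1.67, Xirp2 -1.69, Gsta2 -1.41, Hmga1 -1.29, Cyp4a12b -1.29 and Prrg4 -1.05. PT minus Total at day 5 gave Havcr1 1.84, Vcam1 2.17, Csf1 1.68, Ccl2 1.30, Lcn2 -2.88, Steap4 5.74, Rgs4 4.73, Rasd2 4.20, Mapk11 4.08, Slc44a3 3.98, Pik3r5 4.17, Ear2 -6.48, Arhgap36 -5.55, Slco2b1 -4.04, Gucy1a3 -3.95, Gucy1b3 -3.79, Plbd1 -3.70, Lck 1.99, Krt19 -3.28, Trpm6 2.88, Atp6v0d2 1.03, Wt1 1.62, Synpo 1.11, Aqp3 -1.55 and Tcf21 -1.8. At day 10 this difference was Havcr1 2.14, Vcam1 2.39, Csf1 1.96, Il34 1.31, Spp1 1.09, Lcn2 -1.65, Anxa8 5.29, Rgs4 5.08, Rasd2 4.48, Mapk11 4.44, Slc44a3 4.26, Traf1 4.15, Ear2 -6.50, Sftpd -5.32, Arhgap36 -4.45, Col12a1 -4.24, Slc7a2 -3.93, Slco2b1 -3.79, Trpm6 3.91, Tmem72 1.59, Atp6v0d2 1.92, Foxi1 1.45, Wt1 1.89 and Krt19 -1.94. Female minus male response at day 5 gave Il34 4.44, Ctxn3 7.01, Cyp4a12a 5.95, Gm15895 5.08, Crispld2 4.99, Npas2 4.10, Ciart -5.11, Aldh1l2 -4.40, Id1 -3.63, Xirp2 -3.63, Kynu -3.25, Cdh6 -3.83, Kap 2.07 and Prlr -2.25. At day 10 the sexes differed by Ctxn3 6.80, Slc37a1 5.85, Cyp4a12a 4.72, Gm15895 4.50, Hsd11b1 4.38, Il34 3.74, Baat -3.03, Kynu -2.65, Utrn -2.32, Cndp1 -1.56, 9230105E05Rik -5.62 and Gm11788 -6.67.

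Other splits of the same libraries, fitted on the compared groups alone, were counted against each result. Chance could be excluded for PT day 5 (4322 genes, highest other split 1999), PT day 10 (4551, 2591) and PT day 5 and day 10 in males (3687, 1 and 3225, 5). The same held for Total day 5 (5278, 2723), Total day 10 (5608, 3637 with pairs kept) and Total day 10 against day 5 (85, 1). It also held for PT against Total in contralateral, day 5 and day 10 kidneys (3115, 1771, then 4280, 2387, then 4652, 2370) and the sexes in contralateral PT (403, 5). In each of these 1 split, the real one, gave as many. For the fraction interactions (813, 0 and 801, 0, with the fractions of a kidney moved together) the splits cannot decide. They mixed obstructed and contralateral kidneys within the groups, which removes the obstruction effect itself and widens the spread. With contralateral and day 10 kidneys also kept as pairs the highest other split of the day 10 interaction was 9 in 64 splits. Only the real one was as large, with the same limit. For PT day 10 against day 5 (107 genes in the real split) 4 of 100 splits were as large, the real one among them. That share met the planned bound of under 0.05. The highest other split, with 196, set 1 of 7 against 6 of 7 libraries of high Lars2 and so follows that split of the libraries. Since a grouping apart from the days gave more genes, chance is not taken as excluded here. In the fit of all PT libraries the count was 115 with the split as a term, against 66 without it. For females at day 5 and day 10 (3512, 0 and 3818, 0) the 10 splits are too few for a share under 0.05.

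Chance could not be excluded for the sexes at day 5 (265, highest other 445; 2 of 35 splits), the sexes at day 10 (98, 837; 2 of 35) and sex by day 5 (97, 184; 7 of 100). The higher splits of the sexes set 3 of 3 against 0 of 4 libraries of high Lars2 at day 5 and 0 of 3 against 4 of 4 at day 10. In the fit of all PT libraries the counts were 195 and 496 with the split as a term, against 127 and 332 without it. For sex by day 10 (13, with 2 of 100 splits as large) the splits cannot decide. As for sex by day 5, they mixed the sexes within the groups, which removes the sex difference shared by the states. The highest other split called 659 genes with 7 of 7 against 2 of 7 libraries of high Lars2, which points to a structure of the samples beside the groups. In the fit of all PT libraries the real count was 67 with the split as a term, against 31 without it.

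The 37 macrophage and fibroblast markers that rose in PT libraries at day 10 changed there as in Total by their median (difference -0.28, SD 0.78) and stood at a median of 5.66% of their Total level. A constant share of RNA of other cells in the bead fraction may therefore account for them as a set. Single members of these lists differed in the interaction at day 10. Cd14 (1.71) and Fn1 (1.02, but -1.60 under limma on log2 RPKM) rose more in PT, and Csf1r (-1.19) rose less. For them the source stays open. Among the most abundant were Lyz2 (28.1 CPM in male PT against 566 in male Total) and Col1a2 (15.9 against 336), and the bead purification with its washes is the step meant to remove such RNA. Levels at day 10 argue against that share as the source of the injury, NF-kB, class II and chemokine lists, taken as lists: the medians of their members called higher in PT stood above the median of those markers by 4.28 (SE 0.39), 4.50 (SE 0.34), 3.51 (SE 0.30) and 4.03 (SE 0.34) on the log2 scale, with SDs between members of 1.48, 1.17, 0.64 and 1.71. These standard errors come from resampling genes and leave out the spread between libraries. Single members such as Ccl8 (-4.3 from its Total level) and Clu (-2.86) stood nearer to those markers (median -4.14), and for them the share stays open. The source also stays open for Lcn2 and Krt19. Their PT change minus Total change was -2.88 and -3.28 at day 5, and -1.65 and -1.94 at day 10. That these lists were translated in the tubule after obstruction is a hypothesis, since it was found and tested on the same data, and a state-dependent capture of other cells was not tested.

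Clock genes stood among the sex by day 5 differences in PT, where all 15 tested moved in the sign of a phase shift between groups, and 14 of 15 moved the same way in Total, which argues against noise of the PT libraries. Different hours of collection may therefore lie behind the clock genes, and the labels give no hour. A response of these genes to obstruction stays open beside it. In Total, where contralateral and day 10 libraries of one number were taken as pairs, the female clock score went from -1.78 to -0.32, -3.34 to -1 and -2.98 to -1.02. Male pairs moved both ways, and day 5 libraries were not paired. For the 75 called genes together different hours cannot be told apart from a response that differs by sex: with a clock score in the fit their median fell from 2.2 to 2.07, a ratio of 0.939 (SE 0.18 from leaving out libraries), and 74 kept their sign. Standard errors rose from 0.44 to 0.8 and 3 stayed called. Il34 went from 4.44 ± 0.49 to 5.26 ± 0.84 and stayed called, and Cyp4a12a from 5.95 ± 0.60 to 5.66 ± 1.1.

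Sex differences of contralateral PT were smaller at day 5, where the genes called in contralateral kidneys kept 0.286 of their difference while genes called at day 5 had 0.796 of theirs in contralateral kidneys, a gap of 0.51 (SE 0.13 from resampling genes). This gap argues against selection of large values in these libraries. Its SE treats genes as independent and leaves out the spread between animals. The ratio stayed at 0.277 (SE 0.031, from leaving out libraries as for the other ratios) with the library split as a term and was 0.438 (SE 0.095) with the clock score. Both lay below the bound of 0.6 by more than 1 standard error (for the clock score not by 2). For the split this argues against it as the whole cause. The clock score cannot decide on different hours, since its slope rests on the spread within groups. Between groups it differed more, with -3.34 ± 0.93 in contralateral and 1.12 ± 0.3 in day 5 female PT. At day 10 the gap was 0.208 (SE 0.056 from resampling genes), too small to exclude selection, while the ratio was 0.463 (SE 0.061) with the clock score and 0.454 (SE 0.046) with the split. The value with the split argues against it as the whole cause, and the value with the clock score has the same limit as at day 5. Of the 17 genes of the male-biased list 15 had a smaller difference at day 5 and 9 at day 10, with medians of -3.41 in contralateral kidneys, -1.13 at day 5 and -3.51 at day 10, so that this list, fixed beforehand, was not smaller in its median at day 10. A loss of sex-specific tubule expression with injury is a hypothesis for day 5, found and tested on the same data, and at day 10 selection stays open beside it. Different hours of collection stay open beside it on both days.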

How the results depend on the processing

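The Lars2, split and clock settings, and the threshold without a fold minimum outside PT day 5, PT day 10 and the sexes contralateral, were chosen only after the result was seen, and the others were planned. There were 1396 named gene results, and not every setting tested each of them. Among those tested, no called result changed direction and no uncalled one passed in the other direction under most settings. These were RLE or upper-quartile factors, library size only, DESeq2, limma-voom, either filter, only the compared groups, the replicate block, or any left-out library. Under DESeq2 1367 kept their side of the threshold, 21 lost their call and 3 gained one. Under library size only the counts were 1305, 82 and 4, and under limma-voom 1326, 62 and 3. With the library whose omission weakened each most they were 1207, 176 and 8. Of 540 list results 535 kept their side of the threshold under RLE factors and 520 under library size only, no called one turned, and 178 lost their call with an estimated correlation. Fry lost 50 and gained 63. Uncalled results changed sign while uncalled in 91 values of 40 gene results, none above 1.42 in size. The gene results that turned were Hba-a1 (-0.32) and Hbb-bs (-0.58) at PT day 10 in PT libraries of low Lars2 (3 against 2). Under limma on log2(RPKM + 1) those for fraction by day 5 were Ccl9 (-1.13), C1s1 (-0.30), Lbp (-0.27), Fn1 (-1.36), Xaf1 (-0.21), Pik3r5 (-0.16), Gm14005 (-0.33), Lck (-0.82), Cd40 (-0.12) and Edn1 (-0.22). For fraction by day 10 they were C1s1 (-0.25), Lbp (-0.37), Abcc3 (-0.60), Fn1 (-1.60), Gm14005 (-0.60), Lck (-0.52) and Cd40 (-0.11), and for sex by day 5 Cdh6 (0.24). The cause was not tested.

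Counts of called genes moved by over 1.5 times in these cases. The filter of 5 CPM in 3 libraries, which tests fewer genes, gave 2722 (PT day 5), 2689 (PT day 10), 31 (PT day 10 against day 5), 2635 and 2319 (PT day 5 and day 10 in males), 2894 (PT day 10 in females). It gave 3429 (Total day 5), 3603 (Total day 10), 40 (Total day 10 against day 5), and 2385, 2605 and 2888 (PT against Total contralateral, at day 5 and at day 10). Limma on log2(RPKM + 1) gave, in the same order and with PT day 5 in females between, 2113, 2053, 27, 2112, 1727, 2262, 2499, 2650, 2886, 28, 1081, 1839 and 2026, and 308 for the sexes contralateral. Without a fold minimum PT day 5 gave 7992 and PT day 10 8193. In comparisons where it was added later this threshold gave 6385 and 5996 (PT day 5 and day 10 in males), 9859, 10128 and 104 (Total day 5, day 10 and between them) and 7960, 9162 and 10090 (PT against Total contralateral, at day 5 and at day 10). At an adjusted p under 0.01 and 4-fold PT day 5 and day 10 gave 1899 and 2088, with 231 for the sexes contralateral. For PT day 10 against day 5 the count was 185 with Lars2 as a covariate, 107 with only the compared groups, 192 by DESeq2, 115 with the split as a term, 31 with the clock score and 0 in PT libraries of high Lars2 (4 against 3). For Total day 10 against day 5 it was 161 by DESeq2 and 14 without the libraries of lowest Lars2. For the sexes contralateral it was 403 with only the compared groups and 235 with the clock score. At day 5 it was 192 (Lars2), 265 (compared groups), 241 (DESeq2) and 195 (split), and at day 10 98 (compared groups) and 521 (DESeq2). For sex by day 5 it was 160 (Lars2), 191 (DESeq2), 194 (split), 12 (clock score) and 40 (library size only). For sex by day 10 it was 65 (Lars2), 13 (compared groups), 100 (DESeq2), 67 (split) and 17 (clock score). PT day 5 in females gave 2498 with the clock score. Apart from the filter's fewer genes, the cause was not tested.

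With 1 library left out the counts ran from 4411 to 4732 (PT day 5), from 4591 to 4903 (PT day 10), from 23 to 93 (PT day 10 against day 5), from 3819 to 4315 (PT day 5 in males), from 3545 to 4143 (PT day 10 in males), from 3482 to 3912 (PT day 5 in females), from 4086 to 4643 (PT day 10 in females), from 5350 to 5605 (Total day 5). They ran from 5602 to 6078 (Total day 10), from 17 to 95 (Total day 10 against day 5), from 3989 to 4262 (PT against Total contralateral), from 4700 to 5161 (PT against Total at day 5), from 4935 to 5775 (PT against Total at day 10), from 667 to 781 (fraction by day 5). Counts ran from 820 to 1113 (fraction by day 10), from 466 to 698 (the sexes contralateral), from 56 to 111 (the sexes at day 5), from 149 to 465 (the sexes at day 10), from 22 to 91 (sex by day 5) and from 15 to 39 (sex by day 10). Single libraries moved a count by over 1.5 times in 6 comparisons. For PT day 10 against day 5 the count was 36, 37 and 34 without male day 5 replicates 1, 2 and 3, 38 without male day 10 replicate 3, 24, 25 and 38 without female day 5 replicates 1, 2 and 3 and 23 without female day 10 replicate 3. For Total day 10 against day 5 the count was 28, 30 and 36 without male day 5 replicates 1, 2 and 3, 38 without male day 10 replicate 4, 17, 21 and 31 without female day 5 replicates 1, 2 and 3 and 21 without female day 10 replicate 3. For the sexes at day 5 the count was 74, 79 and 80 without male day 5 replicates 1, 3 and 4 and 56, 59 and 57 without female day 5 replicates 1, 2 and 3. For the sexes at day 10 the count was 214 without male day 10 replicate 4 and 149 without female day 10 replicate 3. For sex by day 5 the count was 46 and 49 without male contralateral replicates 3 and 4, 45, 46, 40 and 40 without male day 5 replicates 1, 2, 3 and 4, 37 and 37 without female contralateral replicates 2 and 3 and 22, 26 and 39 without female day 5 replicates 1, 2 and 3. For sex by day 10 the count was 18 without male contralateral replicate 3, 17 without male day 10 replicate 2, 17 and 19 without female contralateral replicates 2 and 3 and 15 without female day 10 replicate 3.

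The replicate number as a block moved no count by over 1.5 times, and where the numbers do not pair the libraries, correlations with the own number ran from -0.34 to 0.46 and were not the best for every library. It could not be fitted between the sexes. Depth of 9.31 to 43.6 M counts per library limits genes at a few counts, and small changes. Among planted 2-fold changes edgeR found 66% for PT day 5 and 6% for sex by day 10, without the 2-fold minimum of the calls.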

Other observations

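These single genes had the following mean CPM, each given for males and then females. Aoc1, a diamine oxidase, stood in PT at 280 and 267 at day 5 against 2.66 and 1.89 contralateral. Trpm6, a magnesium channel of the distal tubule, stood in PT at 4.64 and 7.46 at day 10 against 0.637 and 0.753 contralateral, and in Total at 6.6 and 9.19 against 9.94 and 18.6. Wt1, a podocyte marker, stood at 19.9 and 20.1 in PT and 12.8 and 14.8 in Total at day 10. Cd74 stood at 3120 and 3450 in PT and 3250 and 3990 in Total at day 10.

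Core clock genes had these mean CPM in PT in contralateral, day 5 and day 10 kidneys. Npas2 stood at 1.32, 14.4 and 5.38 in females and 11.1, 7.45 and 10.8 in males. Arntl stood at 4.25, 20.6 and 6.23 in females and 20.4, 6.85 and 13.4 in males. Ciart stood at 24.1, 0.353 and 2.22 in females and 4.31, 2.19 and 0.878 in males. Dbp stood at 20.6, 1.81 and 7.81 in females and 4.92, 6.52 and 4.42 in males. The clock score, the mean log2 CPM of the Arntl arm minus that of the Per arm, was -3.34 ± 0.93, 1.12 ± 0.3 and -1.18 ± 0.74 in female PT and -0.36 ± 1.29, -0.96 ± 0.34 and -0.03 ± 0.36 in male PT (mean ± SD, n = 3 and 4). In Total it was -2.7 ± 0.82, 0.86 ± 0.38 and -0.78 ± 0.4 in females and -0.23 ± 1.05, -0.72 ± 0.37 and 0.38 ± 0.27 in males.

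The PT libraries split within their groups along 1 component holding 28.4% of the variance around group means, 12 libraries with Lars2 from 5870 to 40960 CPM and 9 with 2557 to 6042 CPM. Reads on mitochondrial genes made 0.0231%, 0.0126% and 0.0109% of PT libraries in contralateral, day 5 and day 10 kidneys, and 3.41%, 1.35% and 1.64% of Total libraries. Genes that collect ribosomal RNA reads made 4.07%, 5.39% and 7.06% of PT and 4.86%, 7.58% and 12.5% of Total libraries.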
